A study of Mus musculus with 6 samples.

How the data were processed

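Transcript levels were measured in 6 samples of mouse embryonic fibroblasts, 3 of a tetraploid line and 3 of a diploid line. Per the labels, total RNA from cells grown to near confluence was depleted of ribosomal RNA, copied into labelled sense-strand target and hybridised to Affymetrix whole-transcript mouse gene arrays. The only tool named for the processing is Affymetrix Expression Console, with no version. Its algorithm, background correction and normalization were not given in the sources used here.

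The deposited values are on a log2 scale, 1 value per probe set and array. This was checked on the values: raising 2 to the power of the value gave whole hundredths (tolerance 0.001) for 100% of the values below 1000 on the linear scale. The floor lay at 1 on the linear scale, a log2 value of 0, and between 87 and 129 probe sets per array stood at it. Array medians lay between 7.24 and 7.28 log2 and differed by at most 0.0435. Since this was below 0.1, the values were used as deposited, by a rule set before the data were examined.

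The table held 28944 probe sets. Of these, 21789 carried exactly 1 gene symbol in the platform table, 1621 carried several and 5534 carried none. Single-gene probe sets whose Entrez ID was in the RefSeq table of the mouse assembly GRCm38.p6 numbered 21698. That table served only for names, the chromosome and order of genes, and gene lengths. For each of the 998 genes with more than 1 probe set the one with the highest mean over the 6 arrays was kept, which left 19939 genes. Probe sets shared by several genes were not used. Trp53, Cdkn1a, Ddx3y and Uba1 had 0 single-gene probe sets and were therefore not analysed here.

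Arrays give no counts, so no depth can be stated, and the number of arrays limits the precision. A background level was set after the data had been seen: on each array, the 95th percentile of 1027 olfactory receptor genes, a family with little known activity outside sensory tissue. It lay at 7.18, 7.41 and 7.28 on tetraploid arrays 1 to 3 and at 7.23, 7.26 and 7.01 on diploid arrays 1 to 3. Where all arrays of 1 line lay at or below it, folds were computed with every value raised to the background level and are given as lower bounds. Where all arrays of both lines lay at or below it, no fold is given. Raising the values of such a gene leaves only the background levels. Its difference then becomes 0.12 (limma adjusted p = 0.463) whatever its own values.

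Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, moderated test, two-sided), with the Benjamini-Hochberg adjustment over all genes. A gene was called at an adjusted p below 0.05. Every adjusted p of a gene comes from this limma fit, and every error beside a level is the SD over 3 arrays. An exact permutation test of 3 arrays against 3 cannot give a two-sided p below 0.1. Replicate numbers recur in both lines, but nothing in the labels pairs them. Deviations from the group mean correlated across genes at only 0.100, 0.0308 and -0.0461 between arrays of the same number, so the fit had no replicate block.

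Before the data were examined, 42 gene lists with 1127 entries were fixed, of which 1031 entries were measured, 10 of them through a synonym. They covered mitosis, DNA replication and G1/S, DNA damage repair, centrosome and centriole, p53 targets, CDK inhibitors and pocket proteins, apoptosis regulators, fibrillar matrix, basement membrane, matrix proteases and inhibitors, contractile and smooth muscle genes, YAP and TEAD targets, the TGF-beta and BMP pathway, the WNT pathway, adhesion receptors, receptor tyrosine kinases and ligands, and RAS pathway feedback. They also covered secreted inflammatory factors, interferon response, MHC class I presentation, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, NRF2 and glutathione, unfolded protein and amino acid stress, ribosome biogenesis and MYC targets, proteasome, lysosome, Hox genes, mesenchymal regional transcription factors, imprinted genes, Y-linked genes and X inactivation. Markers of epithelium, endothelium, macrophages and leukocytes, neural and glial cells, skeletal muscle, adipocytes, chondrocytes and osteoblasts, mesothelium, and pluripotent and germ cells completed them. The 41 lists with at least 3 measured members were tested with camera at its preset correlation of 0.01, adjusted over lists. Camera with an estimated correlation and fry stood beside it.

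Chromosomes and consecutive segments of 30 genes were tested in the same way over the 9950 genes with a position whose mean level was above the median. The last segment of a chromosome took up the remaining genes and held up to 59. For each array, the median shift of a chromosome or segment was taken against the mean of the diploid arrays, leaving out the array itself where it was diploid. A segment is named by its first and last gene.

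Named genes follow a rule fixed before the data were examined. It takes the 12 largest rises and the 12 largest falls among called genes whose groups do not overlap, passing over unnamed, olfactory and vomeronasal genes. It adds up to 2 rises and 2 falls per list, a fixed set of growth control, Y-linked and X inactivation genes, and 2 genes per called segment. The text gives examples from these genes.

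The pipeline was tested on simulated data with the spread of the real arrays and 50 genes changed at each of 4 sizes. With limma's moderated SDs, 0 of 50 genes were recovered at a log2 difference of 0.5, 1 at 1, 38 at 2 and 47 at 3, and 6 of 92 calls were unchanged genes. With the SDs of the 3 arrays themselves, 0, 6, 33 and 38 of 50 were recovered, and 9 of 86 calls were unchanged genes. With nothing changed, 0 genes were called by limma in either case. A list shifted by -1 and a chromosome shifted by 0.3 were each recovered alone. The simulated noise was independent between genes. In the real data genes varied together, with an estimated correlation of 0.72 for the mitosis list and 0.31 for chromosome 8. The simulation therefore does not show how often camera calls a set falsely in such data.

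The alternatives fixed beforehand were quantile normalization, median centring, filters at the median and at the 25th percentile of level, the mean of a gene's probe sets, a trend and robust variance model, array weights, treat with a minimum log2 difference of 0.5, a replicate block, all probe sets, all genes with a position, segments of 20 and 50 genes, and leaving out each array in turn. Raising values to the background level was an alternative chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.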

Results

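The series compared 2 lines of mouse embryonic fibroblasts, the connective tissue cells that grow out of cultured embryos: a tetraploid line, which the series title calls transformed, and a diploid line labelled as the normal control. Each line was measured on 3 arrays. Between 10231 and 11319 of 19939 genes lay above the background level on each array. Each ploidy was represented by 1 line, so ploidy, transformation and line cannot be told apart. The labels do not say whether the 3 samples of a line were separate cultures. Every limma p-value therefore measures only the spread between these samples, whatever its source. Camera at its preset correlation compares the genes of a set with other genes. Its p-values do not take in how strongly the genes of a set varied together between samples.

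The first question was how alike the samples of a line were. Across genes, which are not independent replicates, log2 values correlated at 0.923 to 0.940 between tetraploid arrays, at 0.951 to 0.965 between diploid arrays, and at 0.835 to 0.886 between the lines. The first principal component held 58.8% of the variance and separated the lines. The median SD of a gene was 0.345 over the tetraploid arrays and 0.236 over the diploid arrays.

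The main question was which genes differ between the transformed tetraploid line and the diploid line. Among the genes higher in the tetraploid line were cell division, DNA replication and DNA repair genes, together with the cell cycle inhibitor gene Cdkn2a. Among the genes lower in it were p53 target genes, extracellular matrix and matrix protease genes, contractile genes, TGF-beta pathway genes and the Y-linked genes Eif2s3y, Uty and Kdm5d. In all, limma called 2758 genes (13.83% of those tested), 1213 that rose and 1545 that fell in the tetraploid line. Of these, 920 rose and 1244 fell by a log2 difference of at least 1. In each called gene the 3 values of 1 line lay above the 3 of the other, as they did in 7428 genes (37.25%), where chance gives 10%. The median difference over all genes was 0.07. Array medians were nearly equal in both lines, so the differences are relative to other genes and give no amount per cell. The count was 1589 without tetraploid array 2, 1040 without diploid array 1, 839 without diploid array 2 and 1262 without diploid array 3. In this order, these fits kept 53.81%, 35.93%, 29.95% and 44.27% of the called genes. A call lost in them is thus common and not particular to the genes named below. Among the called genes, 341 were above background on no array.

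The 12 rises picked by the fixed rule were ranked by the deposited difference, and all were in genes at or below background on all diploid arrays, so their rank is not that of their measurable fold. Genes above background in both lines rose as well, such as Gstm1 (8.13-fold higher) and Met (7.12-fold). Prokr1, a receptor for prokineticins, stood at 10.70 ± 0.67 against 3.10 ± 1.02 (SD, n = 3; at least 11.6-fold higher, adjusted p = 8.59e-04). Nlrp4c was at least 14.5-fold higher, Hunk at least 6.80-fold, Mgst2, a microsomal glutathione S-transferase, at least 6.58-fold, and Zcwpw1 at least 6.45-fold. Rasgrf1, an exchange factor that activates RAS proteins, was at least 4.52-fold higher, and Rab6b at least 3.56-fold. Meox1, Cela1, Plekhg4, Cyp2f2 and Galnt13 were also picked but lay close to background, Galnt13 below it on all 6 arrays. Raising values to the background level ended these 5 calls (adjusted p 0.066 to 0.463). The calls of Meox1, Plekhg4 and Cyp2f2 also ended without tetraploid array 2 (adjusted p 0.0741, 0.0729 and 0.0747). Meox1 further lost its call without tetraploid array 3 (adjusted p = 0.0613), Plekhg4 without tetraploid array 1 or diploid array 2 (adjusted p 0.0564 to 0.0729 over its 3 fits), and Cyp2f2 without diploid array 1 or 3 (adjusted p 0.0774 and 0.0768).

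The 12 falls picked by the same rule were in genes at or below background on all tetraploid arrays, and lower bounds of some were small. Genes above background in both lines fell as well, such as Prss23 (20.8-fold lower) and Ephx1 (15.8-fold). Grb10, an imprinted adaptor of insulin receptor signalling, stood at 4.42 ± 0.92 against 12.66 ± 0.06 (SD, n = 3; at least 41.4-fold lower, adjusted p = 2.89e-04). Cxcl14, a chemokine, was at least 19.4-fold lower, C1qtnf3 at least 16.9-fold, the lysosomal protease Ctsc at least 13.6-fold, the neuronal motor gene Kif1a at least 10.6-fold and Ctla2a at least 7.35-fold. Fap, a surface protease of activated fibroblasts, was at least 4.08-fold lower, the collagenase Mmp13 at least 3.74-fold, Ano3 at least 3.54-fold, the phosphatase Ptprd at least 2.61-fold, Hoxb6 at least 1.96-fold and Smpdl3a at least 1.84-fold.

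Cell division genes rose together. Of 49 measured mitosis genes 39 rose, 0 fell and 10 did not pass the test, and over the list alone, adjusted over the list alone, 45 rose. The spindle checkpoint kinase gene Bub1b stood at 11.63 ± 0.08 against 9.63 ± 0.41, and the separase gene Espl1 at 9.77 ± 0.14 against 7.85 ± 0.32. Of 39 DNA replication genes 25 rose and 14 did not pass (32 rose, adjusted over the list alone). The primase gene Prim1 was 5.51-fold higher and the origin licensing gene Cdt1 4.31-fold. Of 28 DNA damage repair genes 16 rose and 12 did not pass (21 rose, adjusted over the list alone), among them Rad54b, at least 2.64-fold higher, and Rad51c, at least 2.58-fold, which act in recombination. Of 30 centrosome genes 10 rose and 20 did not pass (15 rose and 1 fell, adjusted over the list alone). Plk4, the kinase that starts centriole duplication, was 3.07-fold higher and Cdk5rap2 3.03-fold. List medians were 1.33, 1.42, 1.26 and 0.69 in this order, and camera called all 4 lists up (adjusted p 1.28e-19, 2.70e-14, 5.63e-11 and 1.91e-05). The adjusted p was 0.319, 0.324, 0.319 and 0.358 with an estimated correlation. The calls of Plk4, Cdk5rap2 and Rad51c ended without diploid array 2 (adjusted p 0.0698, 0.0834 and 0.0557), those of Plk4 and Cdk5rap2 also without diploid array 1 (adjusted p 0.0625 and 0.0769).

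Target genes of the p53 protein, which halts division or starts cell death after damage, fell as a group. Of 27 measured targets 18 fell, 1 rose and 8 did not pass the test (21 fell and 3 rose, adjusted over the list alone). Mdm2, the ubiquitin ligase gene that p53 itself switches on, stood at 8.96 ± 0.10 against 11.36 ± 0.14 (SD, n = 3; 5.29-fold lower, adjusted p = 0.00103). Eda2r was at least 7.68-fold lower, the cell death gene Pmaip1 at least 6.65-fold and the nuclease gene Aen 6.35-fold, while Sesn1 stood at 9.17 ± 0.80 against 7.25 ± 0.09 and was the member that rose. The list mean lay between 8.15 and 8.32 on the tetraploid arrays and between 9.64 and 9.82 on the diploid arrays. The list median was -1.53 (camera adjusted p = 1.18e-10). The adjusted p was 0.149 with an estimated correlation. The call of Sesn1 ended without tetraploid array 3 or any 1 diploid array (adjusted p 0.0561 to 0.0778).

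**Figure D1:**
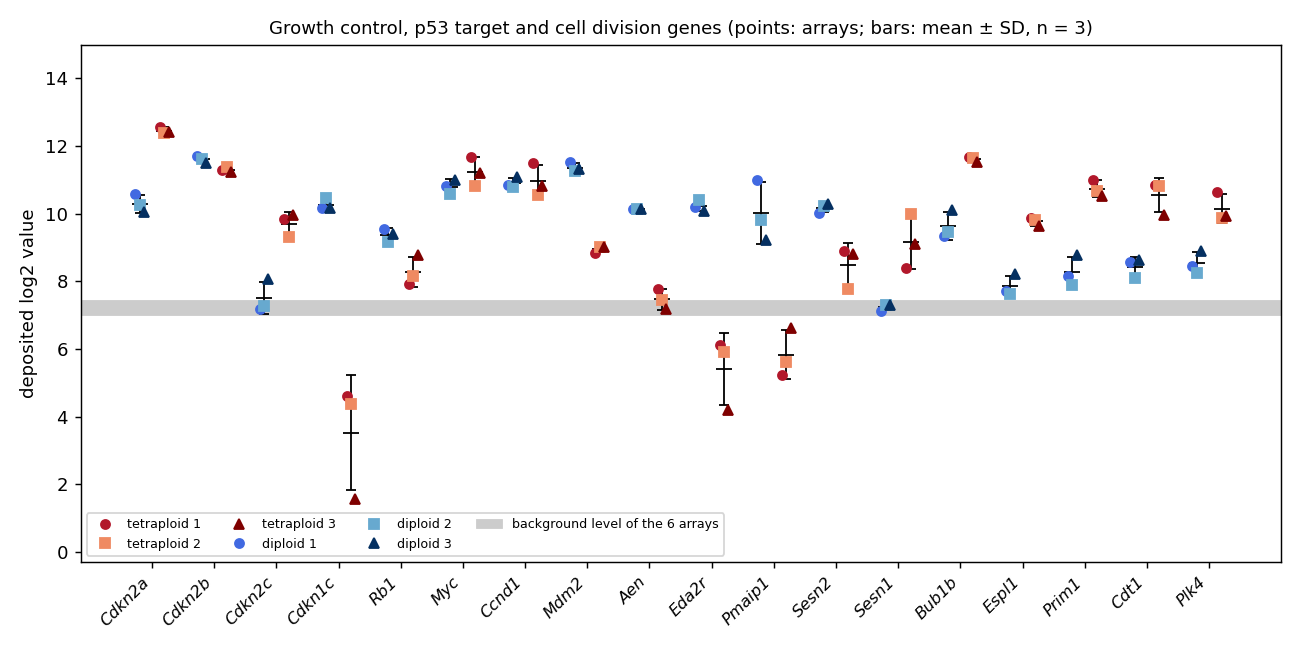
Deposited log2 values of 18 growth control, p53 target and cell division genes on each of the 6 arrays, with bars for the mean and SD of the 3 arrays of a line and a grey band for the background levels of the arrays. Cdkn2a lay at 12.45 on average in the tetraploid line and at 10.30 in the diploid line, and Mdm2 at 8.96 and 11.36.

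Inhibitors of cyclin-dependent kinases went both ways. Cdkn2a, which encodes the tumour suppressors p16INK4A and p19ARF, stood at 12.45 ± 0.10 against 10.30 ± 0.27 (SD, n = 3; 4.45-fold higher, adjusted p = 0.00241), and Cdkn2c was 4.61-fold higher. Cdkn1c, an imprinted inhibitor, was at least 7.86-fold lower, and the retinoblastoma gene Rb1 2.12-fold lower. Of the 10 measured members of this list 5 rose, 2 fell and 3 did not pass, with the same counts adjusted over the list alone. The list had a median of 0.79, a mean of 0.10 and a camera adjusted p of 0.112. Fry called it up (adjusted p = 0.00425), as did camera with only genes above the median level (adjusted p = 0.0312). Cdkn2b (-0.31, adjusted p = 0.317), the cyclin gene Ccnd1 (0.06, adjusted p = 0.924) and the growth gene Myc (0.43, adjusted p = 0.351) did not pass the test. Of 25 apoptosis regulators 4 fell, 1 rose and 20 did not pass (7 fell and 4 rose, adjusted over the list alone). The survival gene Bcl2l2 was 2.59-fold lower, and Bmf, at or below background on all diploid arrays, was at least 1.33-fold higher. The median of that list was -0.24 (camera adjusted p = 0.369), and fry called it down (adjusted p = 0.00860). The call of Rb1 ended in 5 of the 6 fits without 1 array, all but that without tetraploid array 3 (adjusted p 0.0860 to 0.140). The call of Bmf ended in all but that without tetraploid array 1 (adjusted p 0.0960 to 0.124) and with values raised to the background level (adjusted p = 0.171).

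Many genes of the extracellular matrix and of the proteases that cut it fell. Of 33 measured fibrillar matrix genes 17 fell, 1 rose and 15 did not pass (20 fell and 2 rose, adjusted over the list alone). The microfibril gene Mfap5 stood at 5.61 ± 2.63 against 10.51 ± 0.04, the proteoglycan gene Lum was at least 3.34-fold lower, and the matrix gene Fbln1 was 3.18-fold higher. Of 17 basement membrane genes 10 fell and 7 did not pass (12 fell, adjusted over the list alone), among them the collagen gene Col4a2, 10.2-fold lower, and Lama1, which lay below background on all 6 arrays. Of 25 matrix proteases and inhibitors 12 fell and 13 did not pass (15 fell, adjusted over the list alone), among them Mmp13 (at least 3.74-fold lower), while Mmp10 lay below background on all 6 arrays. Raising values to the background level ended the calls of Lama1 and Mmp10 (both adjusted p 0.463). The fibrillar matrix mean was 10.49, 10.38 and 11.06 on tetraploid arrays 1 to 3 and 11.79 to 12.04 on the diploid arrays. The medians were -1.14, -1.32 and -1.10 (camera adjusted p 6.02e-08, 1.54e-06 and 5.77e-08). The adjusted p was 0.303, 0.149 and 0.205 with an estimated correlation. Without diploid array 2 the calls of Mfap5, Lum, Fbln1, Col4a2 and Lama1 ended (adjusted p 0.104, 0.0659, 0.105, 0.0778 and 0.0633). Without diploid array 3 they ended too (adjusted p 0.101, 0.0632, 0.0720, 0.0644 and 0.0687), and all but that of Lum ended without diploid array 1 (adjusted p 0.0695 to 0.118). Tetraploid arrays ended the calls of Mfap5 (adjusted p = 0.0739 without array 1), Col4a2 (0.0624 without array 2) and Fbln1 (0.0976 and 0.0747 without arrays 2 and 3).

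Genes of 4 further lists, contractile, YAP and TEAD target, TGF-beta and BMP pathway, and adhesion receptor genes, mostly fell where they were called. Of 20 contractile and smooth muscle genes 11 fell and 9 did not pass (16 fell, adjusted over the list alone). Actg2, a smooth muscle actin gene, stood at 6.41 ± 1.88 against 12.02 ± 0.33, and Myh11, a smooth muscle myosin gene, was at least 4.67-fold lower. Of 17 targets of YAP and TEAD, which respond to cell tension, 9 fell and 8 did not pass (13 fell and 1 rose, adjusted over the list alone). Ccn2, a matricellular growth factor gene, stood at 9.60 ± 0.52 against 13.13 ± 0.26 (11.5-fold lower), and Crim1 was 5.59-fold lower. Of 30 TGF-beta and BMP pathway genes 14 fell, 1 rose and 15 did not pass (20 fell and 1 rose, adjusted over the list alone). Bmp4, a growth factor gene, was at least 4.75-fold lower, Fst stood at 6.60 ± 1.67 against 10.93 ± 0.18, and the receptor gene Tgfbr3 was 3.67-fold higher. Of 27 adhesion receptors 14 fell and 13 did not pass (15 fell and 1 rose, adjusted over the list alone), among them Itga4, at least 3.55-fold lower, and Itgb3, at 7.20 ± 0.53 against 9.94 ± 0.33. The contractile list mean was 8.48, 8.61 and 9.61 on tetraploid arrays 1 to 3 and 10.84 to 11.06 on the diploid arrays. The medians of the 4 lists were -1.32, -1.01, -1.01 and -1.15 (camera adjusted p 7.03e-09, 2.40e-07, 2.18e-08 and 2.40e-07). For all 4 it rose with an estimated correlation, to an adjusted p of 0.303, 0.149, 0.149 and 0.149. The calls of Fst and Tgfbr3 ended without diploid array 2 (adjusted p 0.0564 and 0.0619).

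**Figure D2:**
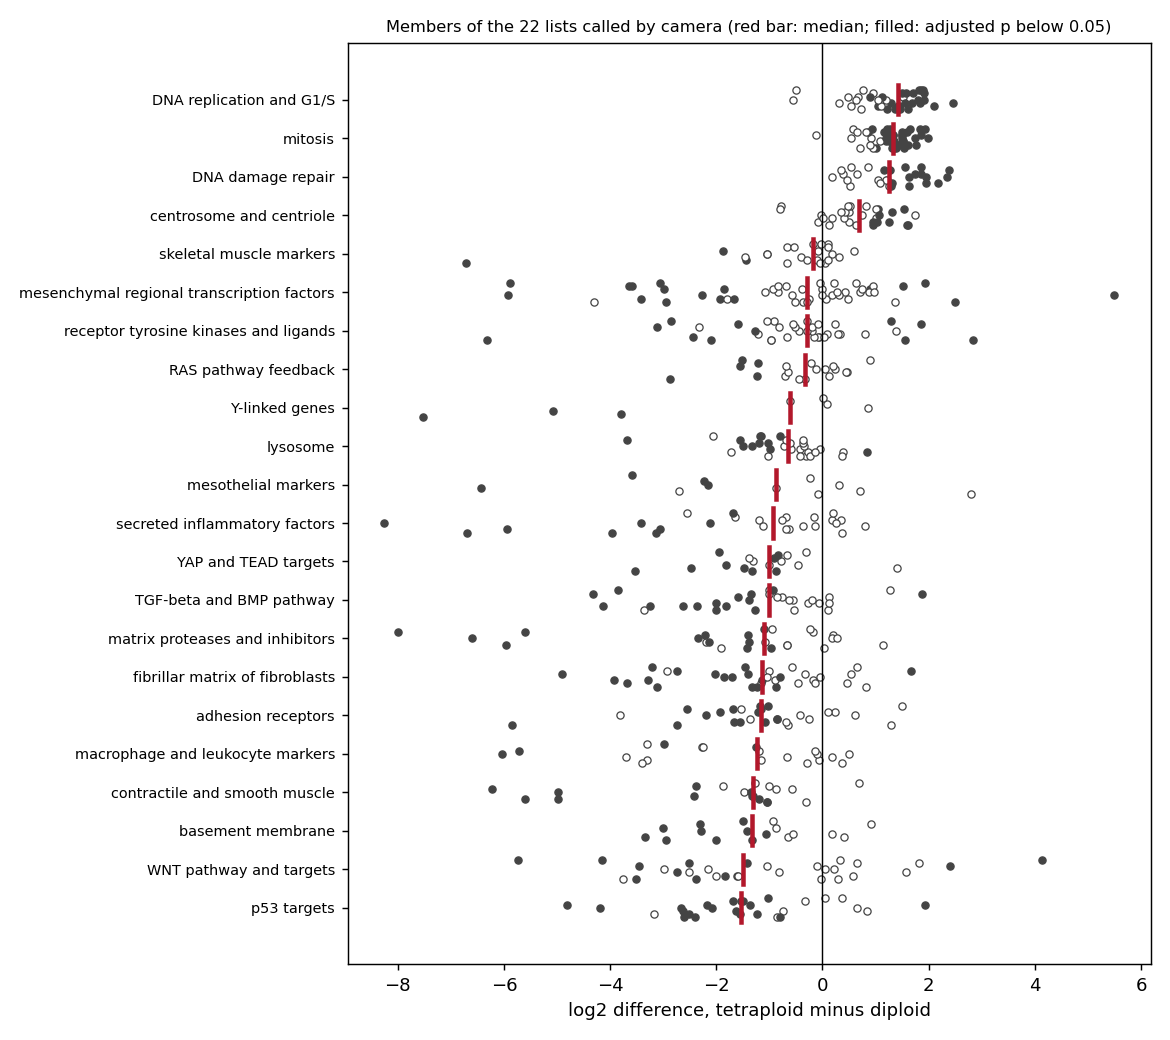
Log2 difference, tetraploid minus diploid, of each measured member of the 22 gene lists called by camera, with filled points for members called by limma and a red bar for the median of the list. The medians ran from -1.53 for the p53 targets to 1.42 for DNA replication and G1/S.

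Some secreted inflammatory factors and macrophage markers fell, and many others of both lists lay near or below background. Of 26 inflammatory factors 9 fell and 17 did not pass (11 fell, adjusted over the list alone). Besides Cxcl14, the cytokine gene Il6 fell, from 7.36 ± 0.31 in the diploid line, and the prostaglandin synthase gene Ptgs2 was 8.32-fold lower. Of 20 macrophage and leukocyte markers 4 fell and 16 did not pass (10 fell, adjusted over the list alone). The lysozyme gene Lyz2 lay below background on all tetraploid arrays and at 6.48, 9.32 and 9.98 on diploid arrays 1 to 3, and Lyz1 lay at 4.51, 7.76 and 8.78 on the diploid arrays. The mean of the macrophage list was 4.41, 4.60 and 4.40 on the tetraploid arrays and 5.08, 6.50 and 7.35 on the diploid arrays. The medians of the inflammatory and macrophage lists were -0.94 and -1.23 (camera adjusted p 6.14e-05 and 2.52e-04). With an estimated correlation the adjusted p was 0.303 and 0.369, and fry did not call the macrophage list (adjusted p = 0.0937), nor did camera with only genes above the 25th percentile of level (adjusted p = 0.576). With values raised to the background level the medians were 0.11 and 0.03 and the adjusted p 0.0662 and 0.377, and the calls of Il6, Lyz1 and Lyz2 ended (adjusted p 0.740, 0.235 and 0.0761). The calls of Lyz1 and Lyz2 also ended without diploid array 2 (adjusted p 0.0592 and 0.0973). That of Lyz2 further ended without diploid array 3 (0.0937), tetraploid array 2 (0.0691) or tetraploid array 3 (0.0525).

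Interferon response genes were not called as a group. Of 31 measured, 2 fell, 1 rose and 28 did not pass, with the same counts adjusted over the list alone. The antiviral gene Ifit2 stood at 8.54 ± 0.06 against 7.50 ± 0.11, while Ifi35 was at 7.54 ± 0.30 against 8.67 ± 0.38. The list mean was 6.47, 6.21 and 5.89 on the tetraploid arrays and 5.94, 6.44 and 7.45 on the diploid arrays, where the macrophage list lay at 5.08, 6.50 and 7.35. The list median was -0.38 (camera adjusted p = 0.170), and without diploid array 1 camera called it down (adjusted p = 0.00598). Of 9 genes of MHC class I presentation 1 fell and 8 did not pass, with the same counts adjusted over the list alone. That list had a median of 0.07, a mean of -0.27 and a camera direction of down (adjusted p = 0.729). The call of Ifit2 ended without any 1 diploid array (adjusted p 0.0515 to 0.0730) and that of Ifi35 without any 1 array (adjusted p 0.0527 to 0.121).

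Growth factor signalling genes went both ways, with more falls. Of 37 receptor tyrosine kinase and ligand genes 7 fell, 4 rose and 26 did not pass (10 fell and 5 rose, adjusted over the list alone). Met, the receptor for hepatocyte growth factor, stood at 11.10 ± 0.50 against 8.27 ± 0.43 and was 7.12-fold higher, and the growth factor gene Fgf7 was 3.62-fold higher. The receptor gene Epha3 was at least 8.68-fold lower and the growth factor gene Fgf2 at least 2.21-fold. Of 19 RAS pathway feedback genes 5 fell and 14 did not pass (6 fell, adjusted over the list alone), among them the phosphatase gene Dusp4, at 7.22 ± 0.75 against 10.09 ± 0.18, and Spry1, at 7.84 ± 0.64 against 9.38 ± 0.29. Of 30 WNT pathway genes 10 fell, 2 rose and 18 did not pass (12 fell and 3 rose, adjusted over the list alone). The receptor gene Lgr5 was at least 2.16-fold lower and the secreted WNT modulator gene Sfrp2 5.26-fold higher, while Frzb lay below background on all 6 arrays (adjusted p = 0.463 with values raised to that level). The medians were -0.30, -0.33 and -1.50 (camera adjusted p 0.0177, 0.0177 and 0.00290). The adjusted p was 0.324, 0.358 and 0.335 with an estimated correlation. The receptor list lost its call without tetraploid array 1 or diploid array 3 (adjusted p 0.0605 and 0.0634). With only genes above the median level, the receptor and WNT lists both lost their calls (adjusted p 0.174 and 0.0940). The WNT median was 0.01 with values raised to the background level. Sfrp2 lost its call in all fits without 1 array but that without tetraploid array 1 (adjusted p 0.0544 to 0.120), and Spry1 in those without tetraploid array 3 or any 1 diploid array (adjusted p 0.0626 to 0.113).

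Camera called the lysosomal list down at its preset correlation, while glycolysis and NRF2 lists were not called. Of 30 lysosomal genes 10 fell, 1 rose and 19 did not pass (15 fell and 1 rose, adjusted over the list alone). The cathepsin gene Ctsf was at least 3.17-fold lower and the lysosomal membrane gene Scarb2 2.92-fold lower. The list mean lay at 9.51 to 9.85 on the tetraploid arrays and at 10.49, 10.53 and 10.38 on diploid arrays 1 to 3. The macrophage list, whose cells are rich in lysosomes, was lower too (median -1.23, but 0.03 with values raised to the background level). Its means of 5.08, 6.50 and 7.35 on diploid arrays 1 to 3 did not move with those of the lysosomal list. The list median was -0.65 (camera adjusted p = 1.94e-06), and with an estimated correlation the adjusted p was 0.303. Scarb2 lost its call without diploid array 2 (adjusted p = 0.0591). Of 27 glycolysis and hypoxia genes 3 rose, 1 fell and 23 did not pass (4 rose and 1 fell, adjusted over the list alone), the lactate transporter gene Slc16a3 at least 4.90-fold lower and the glycolytic enzyme gene Pfkm 2.82-fold higher. Of 28 NRF2 and glutathione genes 2 rose, 3 fell and 23 did not pass, with the same counts adjusted over the list alone. Gstm1, a glutathione S-transferase gene, was 8.13-fold higher and the epoxide hydrolase gene Ephx1 15.8-fold lower. Camera adjusted p values were 0.818 and 0.263 and medians -0.11 and 0.21.

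The remaining metabolic and stress lists were not called by camera. Of 18 cholesterol synthesis genes 2 rose, 1 fell and 15 did not pass (5 rose and 1 fell, adjusted over the list alone; median 0.36, camera adjusted p = 0.122, and 0.0475 without tetraploid array 2). Of 35 oxidative phosphorylation genes 2 rose and 33 did not pass (0 in either direction by limma adjusted over the list alone, 7 at an unadjusted p below 0.05; median 0.18, camera adjusted p = 0.187), and fry called this list up (adjusted p = 0.00442). Of 24 unfolded protein and amino acid stress genes 6 fell and 18 did not pass (7 fell and 1 rose, adjusted over the list alone; median -0.37, camera adjusted p = 0.126, and 0.00694 with values raised to the background level). Of 28 ribosome biogenesis and MYC target genes 1 rose and 27 did not pass (0 in either direction by limma adjusted over the list alone, 6 at an unadjusted p below 0.05). The gene that rose was Mycn, which lay below background on all 6 arrays (adjusted p = 0.463 with values raised to that level). The median was 0.34 (camera adjusted p = 0.0547), and camera called the list up without tetraploid array 2, tetraploid array 3 or diploid array 3 (adjusted p 0.00468 to 0.0385) and with a trend and robust variance model (adjusted p = 0.0261). The call of Mycn itself ended without tetraploid array 1 or 3 or any 1 diploid array (adjusted p 0.0571 to 0.114). Of 31 proteasome genes 2 fell and 29 did not pass, with the same counts adjusted over the list alone (median 0.12, camera adjusted p = 0.485). The proteasome gene Psmd8, on chromosome 7, was 2.34-fold lower.

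Genes that mark position in the embryo changed in both directions. Of 37 Hox genes 6 rose, 6 fell and 25 did not pass (7 rose and 6 fell, adjusted over the list alone). Hoxc4 stood at 10.28 ± 0.52 against 8.12 ± 0.24 (4.46-fold higher), and Hoxb6 was at least 1.96-fold lower. The Hox list had a median of 0.17, a mean of -0.56 and a camera direction of up (adjusted p = 0.927), while fry called it down (adjusted p = 0.0112) and camera called it up with only genes above the median level (median 0.79, adjusted p = 0.0128). Of 47 mesenchymal regional transcription factors 12 fell, 5 rose and 30 did not pass (17 fell and 6 rose, adjusted over the list alone), with Foxd1, a kidney stroma and limb factor gene, at least 1.43-fold lower. Camera called this list down (median -0.29, adjusted p = 0.0293). With an estimated correlation the adjusted p was 0.303, and the call ended without tetraploid array 1 or 3 (adjusted p 0.0887 and 0.0534) and with values raised to the background level (median 0.12, adjusted p = 0.992). It also ended with only genes above the median or 25th percentile of level, where the median turned to 0.29 and 0.19 (adjusted p 0.446 and 0.953), and with a trend and robust variance model (adjusted p = 0.0634). Of 25 imprinted genes 6 fell and 19 did not pass (7 fell and 3 rose, adjusted over the list alone), among them Grb10 and Cdkn1c. The imprinted list had a median of -0.22 and a camera adjusted p of 0.112. Camera called it down without tetraploid array 3 (adjusted p = 0.04999) and without diploid array 1 (adjusted p = 0.0480), and fry called it down (adjusted p = 0.00832).

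Among markers of other cell types, the actin gene Acta1 and the receptor gene Flt1 fell from levels well above background, and camera called the skeletal muscle and mesothelial lists down. Of 23 skeletal muscle markers 4 fell and 19 did not pass, with the same counts adjusted over the list alone, and Acta1 stood at 4.90 ± 0.84 against 11.61 ± 0.52. Camera called the list down (median -0.18, adjusted p = 0.0124). With an estimated correlation the adjusted p was 0.303, and it was 0.0550 without tetraploid array 1, 0.160 with only genes above the median level and 0.543 with values raised to the background level. Of 11 mesothelial markers 4 fell and 7 did not pass, with the same counts adjusted over the list alone, and Upk1b stood at 1.86 ± 1.21 against 8.29 ± 0.27. That list was called down (median -0.88, adjusted p = 0.0256). With an estimated correlation the adjusted p was 0.319, and it was 0.124 without tetraploid array 1, 0.0538 without diploid array 3, 0.749 with only genes above the 25th percentile of level and 0.976 with values raised to the background level. Of 18 endothelial markers 4 fell, 1 rose and 13 did not pass, with the same counts adjusted over the list alone (median -0.08, camera adjusted p = 0.153), and fry called this list down (adjusted p = 0.00832). Flt1 stood at 6.11 ± 1.61 against 10.59 ± 0.15. Of 22 epithelial markers 4 fell and 18 did not pass, with the same counts adjusted over the list alone (median -0.06, camera adjusted p = 0.419), and Esrp2 among them lay below background on all 6 arrays (adjusted p = 0.463 with values raised to that level).

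The last 4 marker lists were not called by camera. Of 21 chondrocyte and osteoblast markers 3 fell, 1 rose and 17 did not pass (6 fell and 2 rose, adjusted over the list alone). The hypertrophic cartilage collagen gene Col10a1 was at least 2.63-fold lower. That list had a median of 0.13, a mean of -0.29 and a camera direction of down (adjusted p = 0.373), and fry called it down (adjusted p = 0.0245). Of 17 neural and glial markers 1 fell and 16 did not pass, as adjusted over the list alone (median 0.09, mean -0.33, camera down, adjusted p = 0.535). Of 15 adipocyte markers 2 fell and 13 did not pass, as adjusted over the list alone (median 0.29, camera adjusted p = 0.818). Of 17 pluripotency and germ cell markers 1 fell, the factor gene Klf4 from 9.78 ± 0.16 to 6.80 ± 0.51, and 16 did not pass, as adjusted over the list alone. The median of that list was 0.12, its mean -0.06, and camera gave up as its direction (adjusted p = 0.927).

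Over the 41 lists tested, camera called 4 up and 18 down at its preset correlation. With an estimated correlation camera called 0 of them, with adjusted p of 0.149 to 0.369 for the 22 lists called at the preset and 7 lists at an unadjusted p below 0.05. Fry, which does not compare a list with other genes, called 28 lists, 21 of them shared with camera.

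Of the Y-linked genes, Eif2s3y, Uty and Kdm5d fell. Eif2s3y, a translation factor subunit gene, stood at 2.47 ± 1.10 in the tetraploid line against 9.99 ± 0.07 in the diploid line (SD, n = 3; at least 6.49-fold lower, adjusted p = 6.96e-04). Uty was at least 2.31-fold lower and Kdm5d at least 1.40-fold, both histone demethylase family genes, and all 3 genes lay below background on each tetraploid array. Uba1y lay at 9.80 ± 0.34 and 9.79 ± 0.10 (adjusted p = 0.987), while Usp9y, Zfy1 and Zfy2 lay below background on all 6 arrays and did not pass (adjusted p 0.138, 0.341 and 0.937). Of the 7 measured genes 3 fell and 4 did not pass, with the same counts adjusted over the list alone. The list median was -0.62 (camera adjusted p = 0.00290), 0.01 with values raised to the background level, and with an estimated correlation the adjusted p was 0.198. Xist, the RNA that silences 1 X chromosome in female cells and the only measured gene of the X inactivation list, lay below background on all 6 arrays, at 3.99 ± 1.77 and 4.97 ± 0.35 (adjusted p = 0.474).

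**Figure D3:**
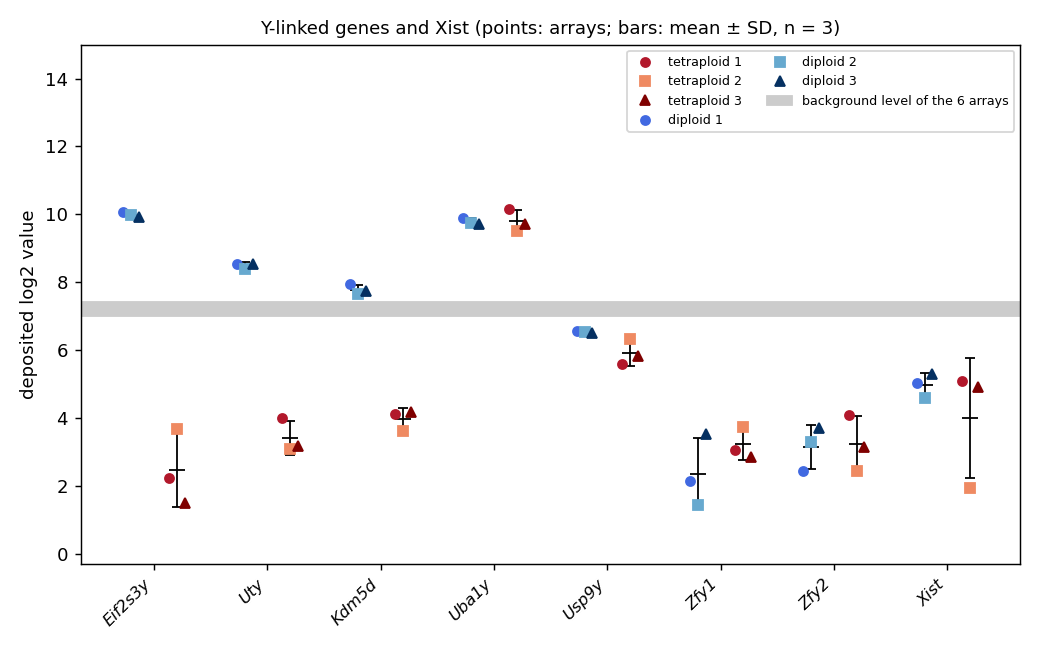
Deposited log2 values of the 7 measured Y-linked genes and of Xist on each of the 6 arrays, with bars for the mean and SD of the 3 arrays of a line and a grey band for the background levels. Eif2s3y, Uty and Kdm5d lay above the band on the diploid arrays and below it on the tetraploid arrays, and Uba1y lay above it on all 6.

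The next question was whether whole chromosomes shifted, as a transformed line can gain or lose chromosomes. Genes on chromosome 15 were higher in the tetraploid line, with a median of 0.43, 92 of 411 genes that rose and 12 that fell. Of these genes 73.97% lay above the median of all genes. Chromosome 3 was higher too (median 0.36, 87 rose and 26 fell of 474). Chromosome 7 was lower (median -0.32, 135 fell and 20 rose of 716), as was chromosome 1 (median -0.28, 91 fell and 15 rose of 558). Genes that changed most within called segments include Nadk2 (5.28-fold higher) and the cohesin gene Rad21 (2.62-fold higher) on chromosome 15. Others are the histone gene H2bc18 (4.78-fold higher) on chromosome 3 and the serine protease gene Prss23 (20.8-fold lower) on chromosome 7. The thiamine transporter gene Slc19a2 (6.21-fold lower) lies on chromosome 1. These genes were picked for their large changes, so their folds do not show the size of the chromosome shifts.

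Camera called 10 of 20 chromosomes, 3, 6, 8, 13, 15, 17 and 19 up and 1, 5 and 7 down, with adjusted p of 2.03e-07 for chromosomes 7 and 15, 2.14e-05 for chromosome 1 and 1.05e-04 for chromosome 3. Camera called 0 with an estimated correlation, with an adjusted p of 0.762 for chromosome 15 and 0.985 for the other 9, and 1 chromosome at an unadjusted p below 0.05. Calls of 6 chromosomes ended in fits without 1 array, and the count was 6 without tetraploid array 3. Chromosomes 5, 13, 17 and 19 lost theirs without that array (adjusted p 0.142, 0.0847, 0.294 and 0.440). Chromosomes 5, 6, 8 and 19 lost theirs without tetraploid array 2 (0.109, 0.0794, 0.209 and 0.0686), chromosome 6 also without tetraploid array 1 (0.133) or diploid array 3 (0.0552), and chromosome 19 also without diploid array 1 (0.0746) or diploid array 2 (0.0537). With all genes with a position, chromosomes 3, 5, 6, 13, 17 and 19 lost their calls (adjusted p 0.105, 0.221, 0.332, 0.105, 0.105 and 0.395), and the count was 4. With only genes above the 25th percentile of level, chromosomes 5, 6, 17 and 19 lost theirs (0.106, 0.139, 0.0609 and 0.222). Array weights ended that of chromosome 6 (0.0779). Quantile normalization, median centring, the mean of probe sets, the replicate block and the background level each ended that of chromosome 19 (0.0503 to 0.0822).

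The 3 tetraploid arrays differed from one another chromosome by chromosome. Chromosome 3 was shifted by 0.57, 0.20 and 0.16 on tetraploid arrays 1 to 3, chromosome 8 by 0.00, 0.43 and 0.20, chromosome 14 by -0.44, 0.02 and -0.12, the X chromosome by 0.34, -0.02 and 0.01, and chromosome 1 by -0.10, -0.68 and -0.36. Chromosome 15 was shifted by 0.31, 0.35 and 0.45 and chromosome 7 by -0.44, -0.51 and -0.20. Over the chromosomes, the difference between a pair of tetraploid arrays had an SD of 0.313, 0.257 and 0.189, while that between a pair of diploid arrays had an SD of 0.0182, 0.0200 and 0.0148.

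**Figure D4:**
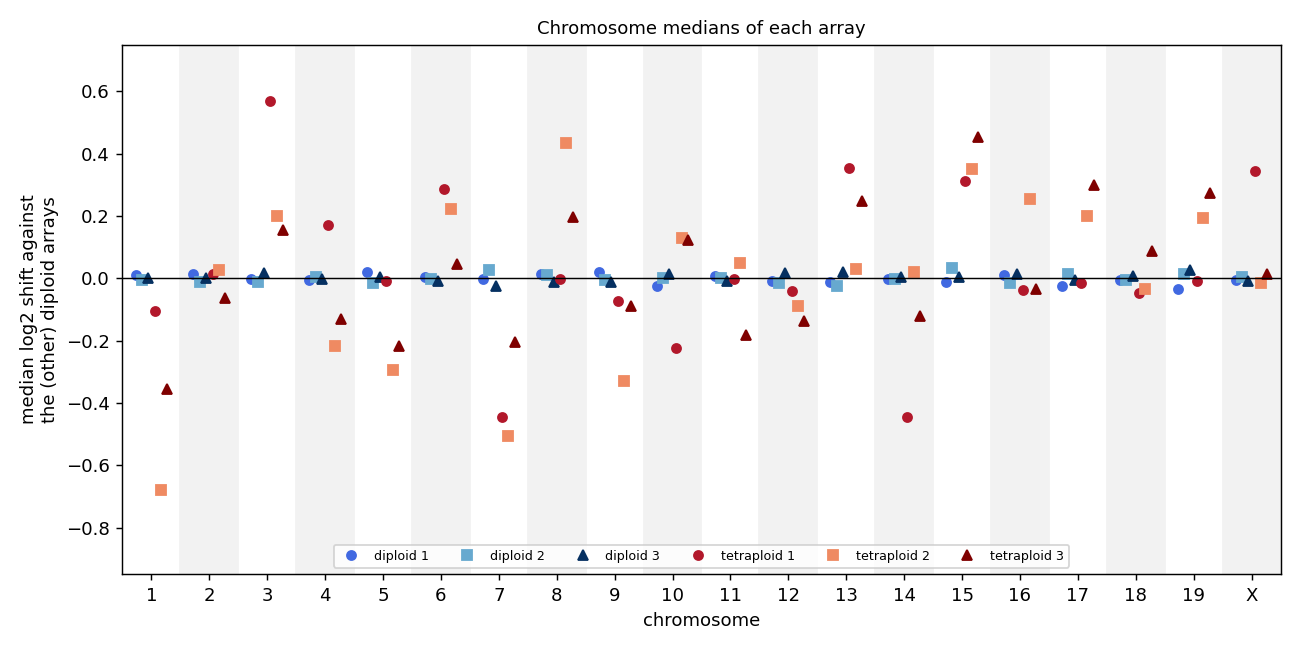
Median log2 shift of the genes of each chromosome on each array, against the mean of the diploid arrays or, for a diploid array, of the other diploid arrays. Chromosome 15 lay at 0.31 to 0.45 on the 3 tetraploid arrays, and chromosome 8 at 0.00, 0.43 and 0.20.

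Segments of 30 neighbouring genes showed where along the chromosomes the shifts lay. On chromosome 15 all 13 segments lay above the median of all genes and 8 were called up. On chromosome 7 all 23 segments lay below it and 10 were called down. On chromosome 3 all 15 lay above it and 5 were called up. On chromosome 1 none of the 18 lay above it and 6 were called down, 5 of them among the last 6. There tetraploid array 1 was shifted by -0.84 in the segment from Cox20 to Capn2 but by 0.10 in the segment from Lman2l to Nck2, where tetraploid array 2 was shifted by -0.75. On chromosome 4, which was not called as a whole, the 3 neighbouring segments from Adgrb2 to Iffo2 were called down. Their medians were -0.39, -0.43 and -0.64, and all 3 tetraploid arrays were shifted by -0.38 or lower in each. The muscle fatty acid binding protein gene Fabp3 (at least 4.53-fold lower) and Slc66a1 (at least 2.22-fold lower) lie in them. In all, 38 of 321 segments were called, 17 up and 21 down. Camera called 0 segments with an estimated correlation (lowest adjusted p = 0.989), with 7 at an unadjusted p below 0.05.

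**Figure D5:**
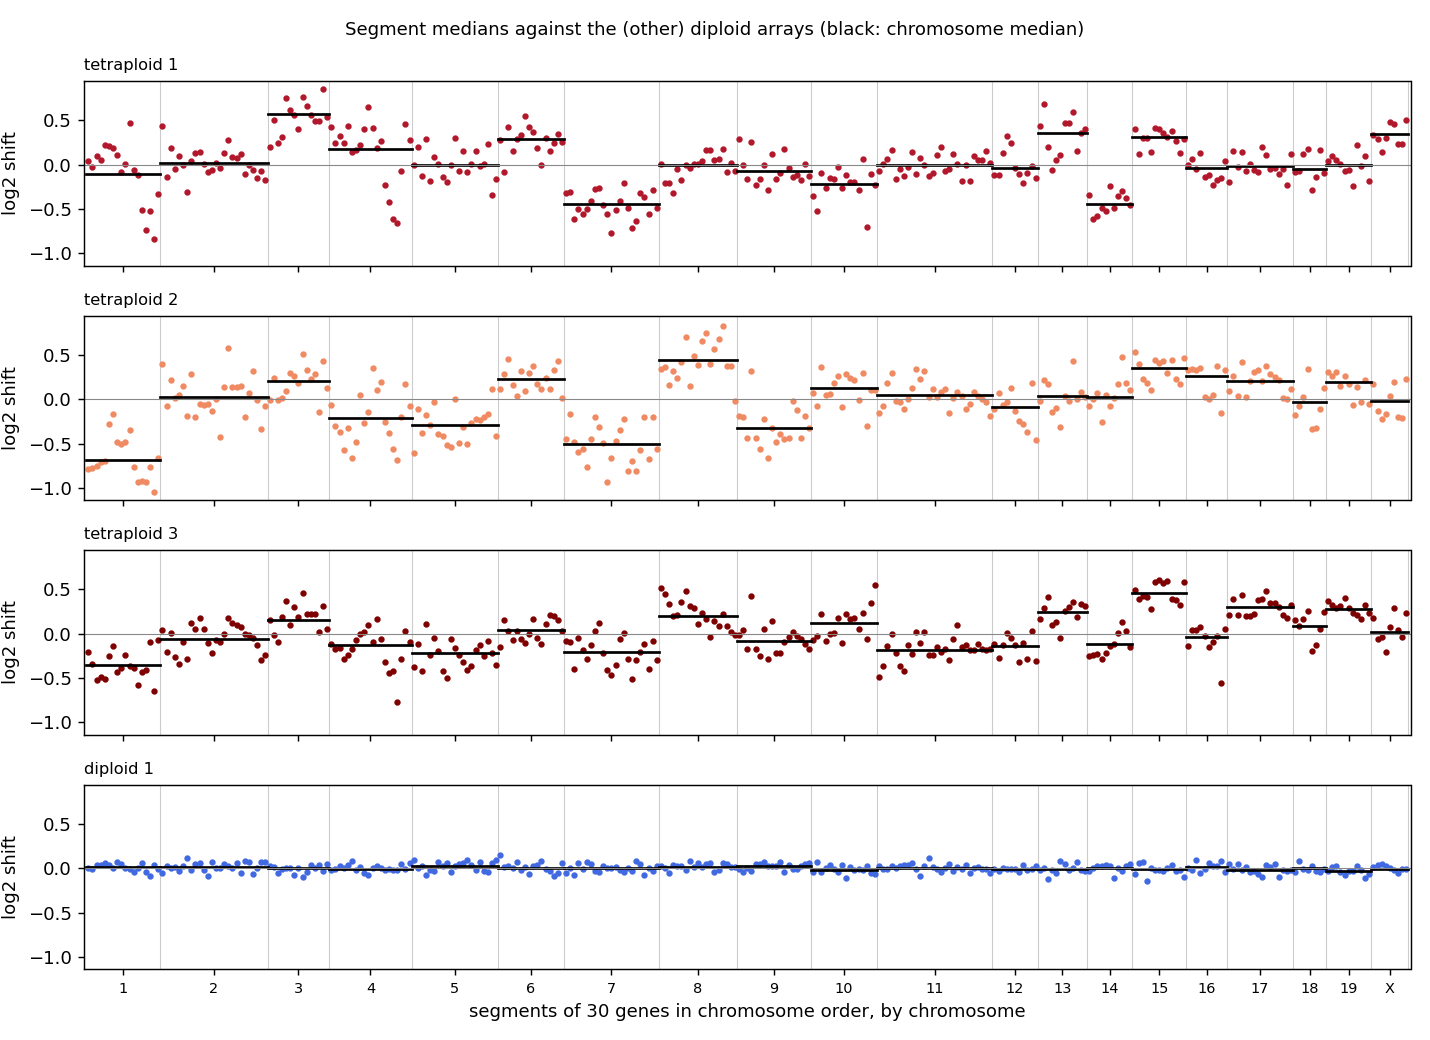
Median log2 shift of each segment of 30 genes, in chromosome order, on the 3 tetraploid arrays and on diploid array 1, against the diploid arrays, with a black line for the chromosome median. Chromosome medians of the tetraploid arrays ran from -0.68 (chromosome 1, array 2) to 0.57 (chromosome 3, array 1), and diploid array 1 stays near 0. Segments also differed inside chromosomes. On chromosome 1, tetraploid array 1 lay at 0.10 from Lman2l to Nck2 and at -0.84 from Cox20 to Capn2.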

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

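Raising values to the background level was chosen after the results were seen; the other settings were fixed before. Of the 2758 called genes, quantile normalization kept 98.15%, median centring 98.30%, the mean of probe sets 98.48%, the trend model 95.58%, array weights 97.68%, the filter at the 25th percentile 83.50%, the filter at the median 63.56%, the background level 73.64%, treat 31.98% and a replicate block 56.93%. Treat called 882 genes (272 rose and 610 fell) and the block 1647 (607 rose), of which 1570 were shared. The trend model gave 1906 rises and the background level 1960. With the median filter 1439 genes changed by at least 1 log2 unit, and 839 to 2166 without 1 array. Leaving out 1 array gave 839 to 2522 called genes, 261 to 1040 rises and 578 to 1552 falls. With an estimated correlation 0 lists, 0 chromosomes and 0 segments were called. Chromosome calls were 4 with all placed genes and 6 with the 25th percentile filter, and 6 to 11 without 1 array. Adding 16 before taking logs does not apply to values already in log2. Replicate numbers pair nothing in the labels. Of 99 named genes that were called, 75 stayed so in every fit without 1 array. Treat ended 19 of these calls, the background level 14, the block 7, the trend model 4 (Col4a2, Lyz2, Mfap5 and Sfrp2) and array weights 1 (Rb1).

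Some list medians changed sign. With values raised to the background level they were 0.11 for inflammatory factors, 0.0800 for interferon, 0.0423 for glycolysis, 0.0057 for WNT and 0.0087 for Y-linked genes, 0.10 for imprinted genes, 0.0267 for macrophage markers, and 0.12 for regional transcription factors and epithelial, endothelial, skeletal muscle and mesothelial markers. The median filter gave 0.29 for regional factors, 0.0904 for imprinted, 0.24 for epithelial and -0.82 for chondrocyte markers. The 25th percentile filter gave 0.19, 0.14 and 0.31 for regional factors, epithelial and mesothelial markers. Array weights gave 0.0694 for epithelial markers, and fry reversed the direction of Hox genes (median 0.17). Over the fits without 1 array, medians ran from -0.0993 to 0.24 (MHC), -0.28 to 0.0366 (glycolysis), -0.41 to 0.0747 (imprinted), -0.14 to 0.26 (epithelial), -0.0971 to 0.20 (neural), -0.45 to 0.0515 (chondrocyte) and -0.0426 to 0.25 (pluripotency).

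Among genes, the background level gave 0.12 for Lama1, Mmp10, Frzb, Esrp2, Usp9y and Xist. Array weights gave -0.0004 for Ccnd1, -0.0391 for Uba1y and -0.0685 for Zfy2. Uba1y was -0.0241 with quantile normalization and -0.0032 with centring. Without 1 array the differences ran from -0.22 to 0.26 for Ccnd1, -0.18 to 0.16 for Uba1y, -1.54 to 0.0332 for Xist and -0.35 to 0.47 for Zfy2.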

Other observations

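After the results had been seen, 12 gene families defined by symbol were tested with camera. None was called with an estimated correlation (adjusted p 0.270 to 0.614), so the calls below hold only at the preset correlation. Several families share genes with the fixed lists, so their calls are not independent of those above. Centromere protein and condensin genes occur in the mitosis list, collagen genes in the matrix lists and chemokine genes in the inflammatory list. Core and linker histone genes were higher in the tetraploid line (19 of 45 rose and 4 fell, 22 and 7 adjusted over the family alone; median 0.70, adjusted p = 0.00103, and 0.270 with an estimated correlation). So were centromere protein genes (14 of 21 rose; median 1.25, adjusted p = 1.71e-06, and 0.270), condensin, cohesin and SMC genes (9 of 13 rose; median 0.98, adjusted p = 3.07e-06, and 0.270) and mu class glutathione S-transferase genes (4 of 7 rose and 1 fell; median 1.68, adjusted p = 0.00478, and 0.270). Collagen genes were lower (17 of 44 fell; median -0.84, adjusted p = 2.64e-08, and 0.270 with an estimated correlation), as were chemokine genes (8 of 32 fell; median -0.33, adjusted p = 0.0140, and 0.270). Heat shock genes (12 of 73 fell and 1 rose; median -0.08, adjusted p = 0.0404, and 0.323 with an estimated correlation) and serpin genes (4 of 48 fell; median -0.21, adjusted p = 0.0487, and 0.285) moved less. Kinesin (12 of 38 rose and 5 fell), protocadherin (11 of 34 rose and 3 fell), semaphorin (1 of 20 rose and 3 fell) and cyclin and Cdc genes (10 of 42 rose and 5 fell) were not called (adjusted p 0.0504, 0.0504, 0.175 and 0.234). Quantile normalization turned only the semaphorin median, from -0.01 to 0.04.

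Some genes stood apart on a single tetraploid array, by a gap of at least 3 log2 units chosen after the data had been seen. Dlk1, an imprinted growth regulator gene, lay at 13.35 and 13.08 on tetraploid arrays 1 and 2 but at 6.14 on array 3. Igf2, an imprinted growth factor gene, lay at 6.85 on tetraploid array 2 and at 12.41 and 12.37 on arrays 1 and 3. The membrane protein gene Itm2a lay at 2.42 on tetraploid array 2 against 11.25 and 11.79, and the WNT antagonist gene Dkk3 at 3.31 on tetraploid array 1 against 9.62 and 9.50. Tetraploid arrays 1 to 3 had 8, 15 and 4 genes low and 23, 8 and 10 high in this way, and the diploid arrays 2, 0 and 0 low and 1, 0 and 0 high.

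Tests on dim probe sets, growth state, Xist, Y chromosome loss and gene counts of other splits were written after the results were seen. The other tests of patterns were written before their own outcomes were seen. Among these, the tests on p53 targets, Y-linked genes and the tetraploid arrays took up patterns that the main results had already shown. The p53 targets were lower in the tetraploid line. A second list of 40 other targets had a median of -0.84 (16 fell and 2 rose), below all 10000 random lists matched on level, the lowest of which had -0.38. With values raised to the background level the 27 targets kept a median of -1.37, below all 10000 random lists, which argues against dim probe sets. Lower p53 activity in the tetraploid line could explain the falls (-0.84), though Trp53 and Cdkn1a were not analysed here and, with an estimated correlation, camera gave the fixed list a p of 0.149 adjusted over 41 lists and the second list, tested alone, an unadjusted p of 0.00620. A growth state that raises division genes (mitosis median 1.33) and lowers p53 targets stays open, because the lines differ in both, although the means of both lists moved apart in only 2 of 6 pairs of arrays within a line.

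Eif2s3y, Uty and Kdm5d were above background only in the diploid line. A general loss of signal was tested on 300 genes matched to these 3 on diploid level, which had a median difference of 0.0345, with 15 below background on all tetraploid arrays. A female culture with an inactive X chromosome could also lack Y-linked transcripts, but the highest Xist value lay -2.08 from background on the tetraploid arrays and -1.72 on the diploid arrays. That stays open, because no array shows that the Xist probe set responds. Loss of the Y chromosome could explain the 3 genes, but 1 of the 4 Y-linked genes, Uba1y, kept its level, and whether it detects its X-linked partner Uba1 cannot be tested because Uba1 was not analysed here.

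The tetraploid arrays differed from one another chromosome by chromosome, with an SD of 0.189 to 0.313. Random assignment of genes to chromosomes gave at most 0.0534 in 1000 runs, and removing gene length and level left 0.986 of the SD. Different copy numbers of whole chromosomes could explain much of it. At least 69.48% of the variance of segment medians between tetraploid arrays lay between chromosomes. That share was 9.07% to 10.51% between diploid arrays and at most 14.13% for shuffled segments. A 5 to 4 copy ratio would give 0.32 and a 3 to 4 ratio -0.42. Chromosome 15 was shifted by 0.31 to 0.45 and chromosome 7 by -0.51 to -0.20, in the same direction on all 3 tetraploid arrays. Among chromosomes that differed between these arrays, some shifts went beyond these ratios, to -0.68 for chromosome 1 and 0.57 for chromosome 3. A gain or loss of more than 1 copy would give larger shifts, so these values do not decide against whole copies. Whole copies alone would not, however, give changes inside a chromosome. On chromosome 1, tetraploid array 1 lay at 0.10 from Lman2l to Nck2 and at -0.84 from Cox20 to Capn2. A bias by base composition stays open, since no genome sequence was used here.

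All 10 splits of the 6 arrays into 3 and 3 were run through the same tests. These are too few for a share under 0.05. Each split other than the real one puts arrays of both lines in both groups. The difference between the lines then widens the spread within groups and stays in part between them. Counts of those splits therefore do not show what chance alone gives. For genes 1 of 10 splits, the real one, called as many as 2758, and the others called 0 by limma with 251 to 773 genes at an unadjusted p below 0.05, against 5869. For lists 2 of 10 splits called at least 22, the highest other count being 23. For chromosomes 8 of 10 called at least 10, with up to 13, and for segments 10 of 10 called at least 38, with up to 111 where tetraploid array 1 was grouped with diploid arrays 2 and 3.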
